A study of Mus musculus and Rattus norvegicus with 12 samples.

How the data were processed

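RNA was measured in 12 libraries in 4 groups of 3, namely hearts of flox and cKO mice and rat NRVCs given siNC or siJmjd4. Total RNA was extracted with TRIzol and made into libraries by standard Illumina protocols, per the labels' protocols. Mouse tissue was heart apex taken 14 days after tamoxifen, and NRVCs were treated with siRNA for 48 h, per the labels. HISAT2 2.1.0, StringTie 1.3.4 and edgeR 3.20.9 and the genome builds mm10 and rn6 are named in the submitters' processing notes, with no role stated there. The library kit, its strand setting, the annotation and the rules of counting are not given in the sources used here. The authors deposited 1 table of counts per system, whole numbers per gene symbol that are not normalized, with 54087 symbols in the mouse and 28909 in the rat. Of these, 25957 and 9397 were at 0 in all 6 libraries. Each column was matched to its sample by the name in the labels.

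The groups were taken from the labels alone. The control mice carry no Cre transgene, so the effects of Cre and of the knockout cannot be separated in these data. Genes were filtered with edgeR's filterByExpr, which kept 18094 mouse and 15497 rat genes, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion (edgeR 4.0.16, R 4.3.3) was fitted to each system on its own 6 libraries, with group as the only term, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. CPM values use the TMM-scaled library sizes. Values are given as mean ± SD over 3 libraries, and standard errors of log2 fold changes come from the quasi-likelihood F statistic. With 3 against 3 libraries an exact permutation test cannot go below 0.1, so no such test was made of single genes. Bounds from a count of 0 use a floor of 3 counts per library and cover counting error only.

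Before the data were examined, 29 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, with the p adjusted over the lists having at least 5 tested members. Camera with an estimated correlation and fry were alternatives. The rule names Jmjd4 and Pkm, the 8 highest and 8 lowest fold changes among called genes with no overlap between the groups, a mean of at least 1 CPM and a symbol that is not a predicted name, up to 4 members of each list with the smallest p, and for the systems the 5 smallest p for the difference. The pattern for predicted names did not cover clone names, so the rule also took 4 clone-named loci. The text gives a selection of the genes it took, made after their values were seen, and the others are not reported here. Genes were paired across species by symbol with case ignored, shared calls were tested with Fisher's exact test, and the difference between the responses was tested in 1 edgeR model of all 12 libraries with 4 group means.

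Alternatives fixed beforehand were DESeq2's size factors, DESeq2's Wald test (1.42.0), no filter, a mean of at least 5 CPM, a log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were a correction for each library's trend with transcript length (a smooth of span 0.3, used as an offset), limma voom with sample quality weights, scaling to total counts alone, the mitochondrial genes and their nuclear copies left out, and fits without flox replicate 3 and cKO replicate 2 or without flox replicate 3 and siNC replicate 3. Transcript lengths, positions and gene identities come from GENCODE M21 on GRCm38, the assembly that mm10 names, and 80% of tested mouse genes and 83.9% of tested rat genes had a length, the latter that of the mouse gene of the same symbol. Rat coordinates were not used here.

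Pairs of replicates were checked for duplicates. Their counts differed by 26.1 to 1580 times sampling noise (chi-square per degree of freedom), so all 12 were kept as separate samples. Genes of the mitochondrial genome and their nuclear copies share reads, and the copies held 3.9% to 13.5% of counts in the heart libraries.

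The code was tested on simulated counts with 200 changed genes. Each gene was drawn independently, with the same mean in all libraries apart from library size and the changes set. The simulated libraries thus lacked links between genes, and lacked trends with transcript length except where such a trend was added. The rates of recovery and of false calls need not hold for the real libraries. For the heart comparison, over 18094 genes and all 6 libraries, 86.4% of genes changed 16-fold, 6.1% of those changed 4-fold and 0% of those changed 2-fold were recovered, with 3 false calls among 64. Without flox replicate 3, over 19094 genes, these shares were 93.9%, 74.2% and 7.4%, with 11 false calls among 127. For the NRVC comparison, over 15497 genes, they were 97%, 72.7% and 10.3%, with 6 false calls among 125. Without siNC replicate 3, over 15798 genes, they were 93.9%, 92.4% and 54.4%, with 16 false calls among 176 and 1 list called that had not been shifted. False calls thus exceeded a share of 0.05 in both fits with a control library left out. For the difference between the systems, over 11848 genes, 179 of 200 genes changed 16-fold were recovered, with 23 false calls. With a length trend added to flox replicate 3, over 14481 genes, the length correction recovered 162 of 200 genes changed 4-fold, with 16 false calls. Without the correction 0 were recovered, with 0 false calls. The share of false calls lay above 0.05 with the length correction and for the difference between the systems as well.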

Results

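Gene expression was measured by RNA sequencing in 2 systems in which Jmjd4, a gene of the JmjC oxygenase family, was targeted in heart muscle. The series title names PKM2, a product of the pyruvate kinase gene Pkm, and dilated cardiomyopathy. Hearts came from mice with floxed Jmjd4 alleles, either without a Cre transgene (flox, n = 3) or with a tamoxifen-inducible Cre expressed in cardiomyocytes (cKO, n = 3), and the apex was taken 14 days after tamoxifen, per the labels. Cultured cells were neonatal rat ventricular cardiomyocytes (NRVCs) from Sprague-Dawley rats, given a control siRNA (siNC, n = 3) or an siRNA against Jmjd4 (siJmjd4, n = 3) for 48 h. The 12 libraries held 57174654 to 82187009 counts each. In the mouse the total was 74391803, 72471146 and 80297797 counts in flox replicates 1, 2 and 3 and 72489489, 69284629 and 66364405 counts in cKO replicates 1, 2 and 3. In the rat it was 57174654, 62265533 and 64038149 counts in siNC replicates 1, 2 and 3 and 82187009, 60170021 and 71002146 counts in those labelled siJmjd4. The labels do not say whether the NRVC replicates came from separate cell isolations, so the p-values of that comparison measure only the spread between these samples.

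Flox replicate 3 stood apart from the other 5 heart libraries. Genes of the mitochondrial genome took 41.7% of its counts, against 14.2% to 24.1% in the others, and 1485 tested genes had no count in it, against 125 to 503. Its ratio to flox replicates 1 and 2 went with transcript length, with a median log2 ratio of 1.16 in the 3621 genes with the shortest transcripts and of -1.64 in the 3620 with the longest. In the rat, siNC replicate 3 showed a like trend, from 0.67 to -0.71, and had 461 tested genes without a count, against 78 to 137 in the other 5. A trend with length was not confined to these 2 libraries. The Spearman rho across genes of a library's ratio to the others of its group with transcript length was -0.62 in flox replicate 3 and -0.55 in cKO replicate 2, which had 503 tested genes without a count, and -0.48 in siNC replicate 3 and -0.37 in siJmjd4 replicate 1. Results without the 2 control libraries are given for the counts of genes and for many of the lists.

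**Figure D1:**
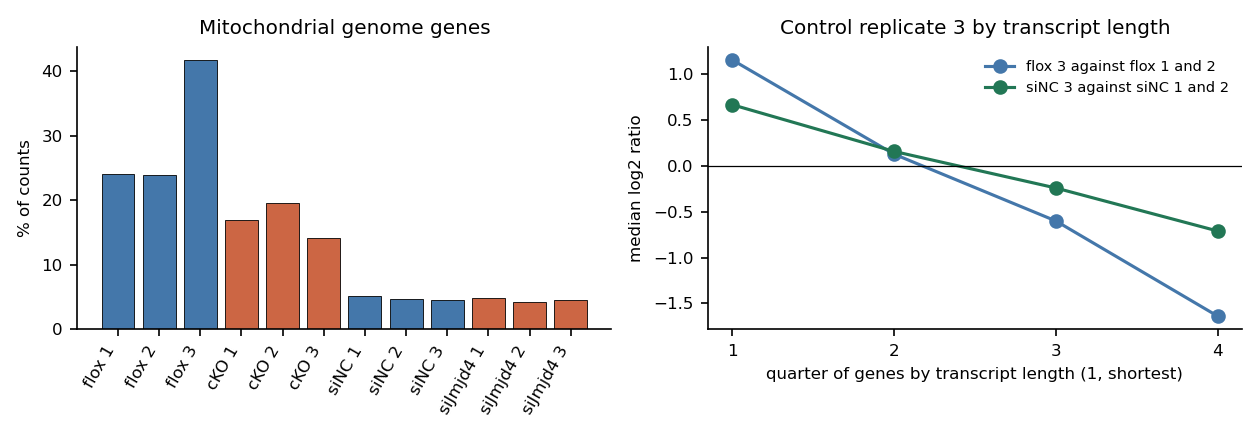
Left, the share of each library's counts in mitochondrial genome genes (percent; blue, control libraries; orange, cKO or siJmjd4 libraries), highest in flox replicate 3 at 41.7%. Right, the median log2 ratio of the third control library to the other 2 in 4 equal bins of genes ordered by transcript length, which goes from 1.16 to -1.64 in the mouse and from 0.67 to -0.71 in the rat.

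Jmjd4 itself had a lower mean in cKO than in flox hearts, but the groups overlapped. It lay at 19, 8.04 and 16.9 counts-per-million (CPM) in flox replicates 1, 2 and 3 (14.64 ± 5.819, SD, n = 3) and at 8.95, 4.92 and 9.63 CPM in cKO replicates 1, 2 and 3 (7.835 ± 2.547, SD, n = 3). The log2 fold change was -0.90 (SE 0.44), with an adjusted p of 0.3973 in edgeR's quasi-likelihood test, and -0.79 without flox replicate 3. The counts cover the whole gene and other heart cell types keep it, and which exons are flanked by loxP sites is not given in the sources used here. The gene lies on chromosome 11 from 59450045 to 59458567 of GRCm38, plus strand, and its start overlaps the start of Snap47 (59407134 to 59451186, minus strand), so reads of the 2 genes may not be separable where the counting ignored strand. Snap47 had a log2 fold change of 0.18. In the NRVCs, Jmjd4 was at 3.46, 4.4 and 0.982 CPM in the siNC libraries (2.949 ± 1.766, SD, n = 3) and at 3.58, 3.43 and 3.52 CPM in the libraries labelled siJmjd4 (3.511 ± 0.07907, SD, n = 3). The log2 fold change was 0.25 (SE 0.52, adjusted p = 0.7698), and -0.16 (adjusted p = 0.6852) without siNC replicate 3. A lower Jmjd4 transcript level was thus not detectable in the libraries labelled siJmjd4, and every rat direction below rests on those labels alone. Pkm, on chromosome 9 from 59656368 to 59679375, did not pass the test in either system. Its counts are of RNA over the whole gene, so they do not show PKM2 apart from other Pkm products. Its log2 fold change was -0.11 in the hearts (882.1 ± 130.8 CPM in cKO against 954.6 ± 36.51 in flox, SD, n = 3) and 0.45 there with scaling to total counts alone, and -0.23 in the NRVCs (947.6 ± 60.32 against 1115 ± 198.8 CPM), or -0.08 without siNC replicate 3.

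**Figure D2:**
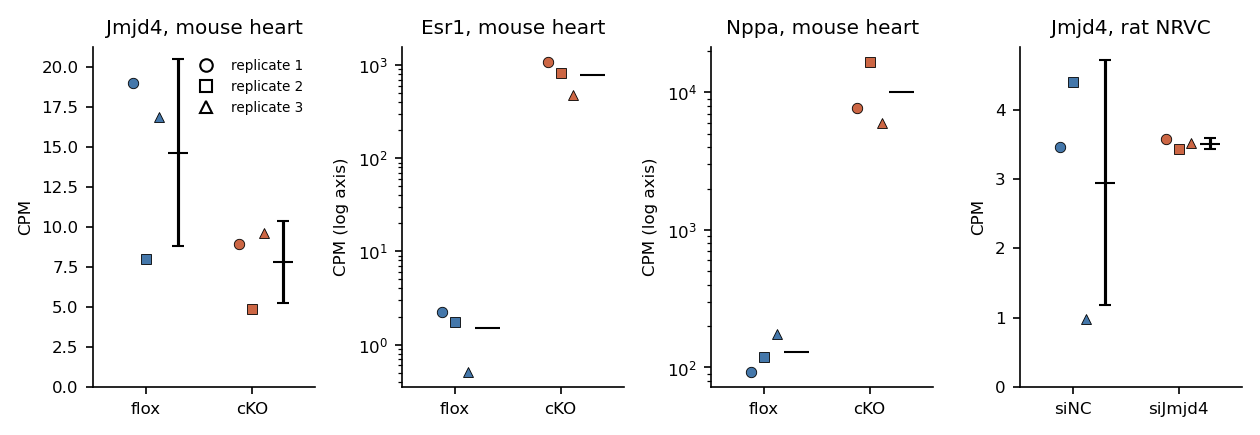
CPM per library of Jmjd4, Esr1 and Nppa in mouse hearts and of Jmjd4 in rat NRVCs (points, libraries, shaped by replicate number; horizontal line, mean; bars, SD, on the linear axes of the Jmjd4 panels only; Esr1 and Nppa on log axes). Jmjd4 overlaps between the groups in both systems, with means of 14.64 and 7.835 CPM in flox and cKO hearts, while Esr1 and Nppa separate them. Esr1 counts may include reads of the transgene.

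Hearts of cKO mice were set against flox hearts to find which genes change after the knockout is induced in cardiomyocytes. Genes of the extracellular matrix and of the fetal cardiomyocyte programme were higher as sets in cKO hearts, with 6 of 37 and 4 of 22 members called (camera, adjusted p = 2.53e-22 and 2.99e-11, but adjusted p = 0.203 and 0.0467 with an estimated correlation). Nppa, which encodes the atrial natriuretic peptide of the stressed ventricle, rose 78-fold, to 10060 ± 5622 CPM from 128.9 ± 42.1 (SD, n = 3; log2 fold change 6.29, SE 0.70, adjusted p = 0.03331). Ltbp2, a matrix protein of elastic microfibrils, rose 79.5-fold (165.3 ± 119.6 against 2.066 ± 1.264 CPM, adjusted p = 0.04557). Ctgf, a matricellular protein of fibrosis, rose 23.4-fold, to 1087 ± 178.7 from 46.52 ± 13.85 CPM (adjusted p = 0.02551). Among lower genes, Ucp3, a mitochondrial carrier tied to fatty acid use, fell 12.1-fold, to 2.098 ± 0.8457 from 25.36 ± 1.835 CPM (adjusted p = 0.0366).

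Of 18094 genes tested, 67 were higher and 25 lower in cKO hearts at an adjusted p under 0.05, and 2715 had an unadjusted p under 0.05, where chance gives 905. The values of the 2 groups did not overlap for any of the 92 called genes, while 26.1% of all tested genes had no overlap and chance gives 10%. Besides Nppa and Ltbp2, the 8 highest fold changes taken by the rule for named genes included those of Esr1 (522-fold, 788 ± 297.7 against 1.495 ± 0.884 CPM), Col8a2 (72-fold) and Comp (63.2-fold). Esr1 encodes oestrogen receptor alpha, and the MCM transgene named in the labels carries parts of an oestrogen receptor. Reads of the transgene may have been counted as Esr1, so its rise cannot be read as a change of the mouse's own gene. With clone-named loci set aside, the lowest were Cngb3 (42.6-fold lower) and Kcnv2 (23.5-fold lower), both channel subunits, then Gpr22 (14.3-fold lower), a receptor of heart and brain, Ces1d (12.6-fold lower), a lipase, and Mme (12.4-fold lower), the peptidase neprilysin. The number of calls turned on the libraries used. Without flox replicate 3, 813 genes were higher and 560 lower, the 92 among them, and without any other single library edgeR called 0, with 1657 to 2587 genes at an unadjusted p under 0.05. DESeq2's Wald test on all 6 libraries called 957 higher and 791 lower. With scaling to total counts alone, which raised the median log2 fold change of all genes to 0.54, 20 were higher and 0 lower, with 2742 at an unadjusted p under 0.05.

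**Figure D3:**
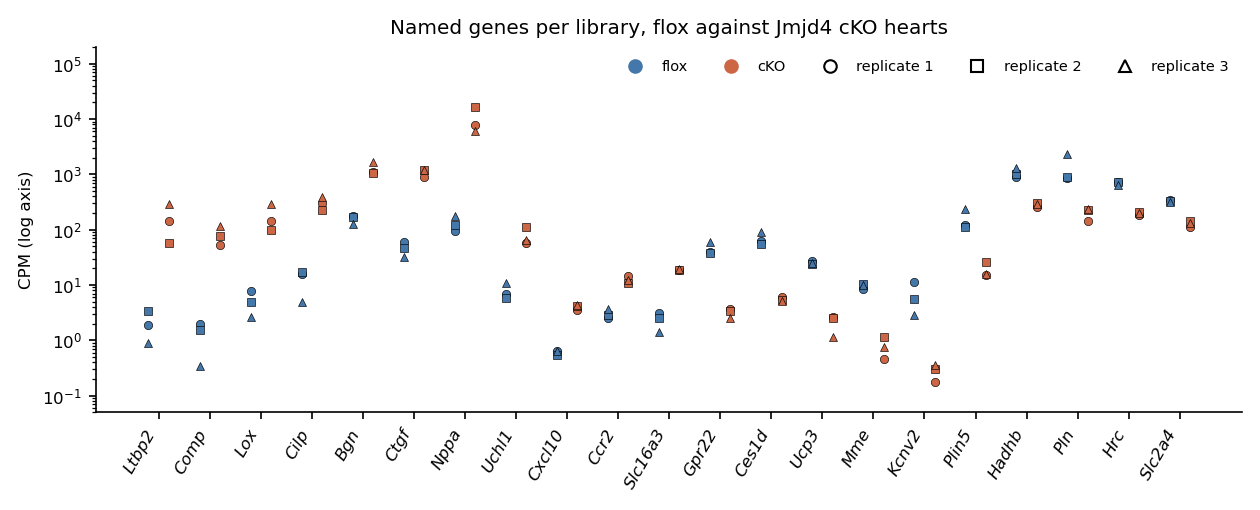
CPM per library on a log axis for 21 genes named in the text (blue, flox; orange, cKO; symbols, replicate number). The genes from Ltbp2 to Slc16a3 lie higher and those from Gpr22 to Slc2a4 lower in all 3 cKO libraries than in all 3 flox libraries, and the 5 from Plin5 on did not pass the test over all genes with all 6 libraries.

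Camera called 20 of the 29 lists in the hearts, and 7 to 14 when the same libraries were split 3 and 3 in any other way. A camera call of a single list is thus weak on its own. The extracellular matrix and fibrosis list rose as a set. All 37 of its tested members had a higher value in cKO hearts, 6 were called over all genes and 29 when adjusted over the list alone, and the median log2 fold change was 2.72 (camera, adjusted p = 2.53e-22, but adjusted p = 0.203 with an estimated correlation). Called members included Comp, a cartilage and tendon matrix protein, Lox, the collagen cross-linking enzyme (log2 fold change 5.08, SE 0.67), Cilp (4.61, SE 0.61) and the proteoglycan Bgn (3.02, SE 0.42, 1273 ± 329.2 against 157 ± 26.15 CPM). The median was 2.26 and 20 members were called without flox replicate 3. In the list of fetal and cardiomyocyte stress genes, 4 of 22 members were called higher, 12 when adjusted over the list alone, and 0 lower. Its median was 1.79, with camera's adjusted p at 2.99e-11 and at 0.0467 with an estimated correlation, the only list to stay called there. With that library left out, 15 members were called and the estimated-correlation p was 0.108. Beside Nppa and Ctgf, the called members were Uchl1, a deubiquitinating enzyme (9.81-fold, adjusted p = 0.04023), and Mybpc2, the fast skeletal myosin-binding protein C (6.92-fold, adjusted p = 0.0483). Tnni1, the slow skeletal and fetal troponin I, had a log2 fold change of 5.30 (SE 1.05) that did not pass (adjusted p = 0.08733).

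Genes of mitochondrial energy supply were lower as sets, with few single calls. In the list of fatty acid uptake and oxidation, 32 of 34 members had lower values and the median log2 fold change was -1.67 (camera, adjusted p = 3.63e-20, adjusted p = 0.132 with an estimated correlation). Ucp3 alone was called over all genes and 25 members when adjusted over the list alone. Plin5, a lipid droplet protein, was at 19.01 ± 5.942 against 154.8 ± 68.61 CPM (adjusted p = 0.05099), and Hadhb, of the mitochondrial trifunctional protein, at 282.9 ± 28.38 against 1075 ± 219.1 CPM (adjusted p = 0.08233). Leaving out flox replicate 3 gave 21 called members and a median of -1.37. In the list of pyruvate oxidation and the TCA cycle the median over 31 members was -1.23 (adjusted p = 1.13e-13, 0.138 as the p with an estimated correlation), 0 were called over all genes and 15 when adjusted over the list alone, and 10 were called without flox replicate 3. Pdp2, a pyruvate dehydrogenase phosphatase, had a log2 fold change of -1.60 (SE 0.36) and Dlst, of the oxoglutarate dehydrogenase complex, of -1.54 (SE 0.38). The branched-chain amino acid and ketone body list had a median of -1.08 over 19 members (adjusted p = 3.3e-11, and 0.11 as the p with an estimated correlation). None of these was called over all genes, 11 were when adjusted over the list alone, and 9 were without flox replicate 3, among them Dbt (-1.37) and Pcca (-1.27). With scaling to total counts alone the medians of these 3 lists were smaller, at -1, -0.54 and -0.53.

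All 77 nuclear-encoded subunits of oxidative phosphorylation and all 13 transcripts of the mitochondrial genome had lower values in cKO hearts, but none was called, either over all genes or adjusted over the list alone. Their medians were -1.75 (camera, adjusted p = 1.01e-18) and -1.74 (adjusted p = 6.9e-06), and the p with an estimated correlation was 0.332 for both. Much of that size came with flox replicate 3, the library with the most short and mitochondrial transcripts. Without it the medians were -0.54, with 3 subunits called, and -0.71, with 0 called. That fit keeps cKO replicate 2, whose ratio to its group also fell with transcript length (rho -0.55), so it does not remove such trends. Ndufs1 of complex I (log2 fold change -1.15, adjusted p = 0.02553) and Sdha of complex II (-1.09, adjusted p = 0.0376) were called without flox replicate 3, and so was Cox7a1, whose log2 fold change moved from -3.20 to -1.60 (adjusted p = 0.04143). The mitochondrial gene regulators had a median of -0.91 over 18 members (adjusted p = 4.24e-05, and 0.11 as the p with an estimated correlation), with 0 called over all genes, 5 when adjusted over the list alone and 4 without flox replicate 3. The latter group held Ppargc1a, the coactivator of mitochondrial biogenesis (-2.04, adjusted p = 0.01081), Perm1 (-1.66, adjusted p = 0.009668) and the retinoid receptor Rxrg (-1.72, adjusted p = 0.009136). With scaling to total counts alone the medians were -0.74 for the nuclear-encoded subunits, -0.85 for the mitochondrial genome and -0.38 for the regulators. With the correction for transcript length the first 2 were -1.08 and -1.05, with 21 subunits and 5 transcripts of the mitochondrial genome called lower.

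Glycolysis genes did not move together. Their median was -0.26 over 25 members (camera, adjusted p = 0.508) and -0.06 with the length correction. It turned to 0.12 without flox replicate 3 and to 0.45 with scaling to total counts alone. Slc16a3, the lactate exporter MCT4, was the 1 called member, 7.88-fold higher (18.92 ± 0.4948 against 2.388 ± 0.8762 CPM, adjusted p = 0.03872). When adjusted over the list alone 2 members were higher and 2 lower, and without flox replicate 3 the counts were 3 and 3. The heart's insulin-responsive glucose transporter Slc2a4 was at 128.4 ± 14.69 against 334.5 ± 15.17 CPM (log2 fold change -1.38, adjusted p = 0.1111, and 0.01379 without flox replicate 3, but -0.84 with total counts alone). The basal transporter Slc2a1 was at 37.59 ± 7.672 against 15.17 ± 1.519 CPM (1.31, adjusted p = 0.1059, and 0.02336 without flox replicate 3).

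Calcium handling and ion channel genes were lower as a set, with a median of -0.81 over 31 members (camera, adjusted p = 1.52e-06, and 0.23 as the p with an estimated correlation). None was called over all genes and 7 were when adjusted over the list alone, and the median was -0.38 with scaling to total counts alone. Without flox replicate 3 the median was -1.02 and 12 were called lower, among them Pln, the brake of the sarcoplasmic calcium pump (log2 fold change -2.13, adjusted p = 0.01076), the calcium-binding Hrc (-1.89, adjusted p = 0.007243), the potassium channel Kcnj3 (-3.17, adjusted p = 0.003142) and the channel subunit Kcnip2 (-1.99, adjusted p = 0.01226). Sarcomere and Z-disc genes had a median of -0.53 over 23 members with 0 called (camera, adjusted p = 0.818), of 0.28 with scaling to total counts alone, of -0.17 with the length correction, and of 0.10 without flox replicate 3, when 3 members were called higher, such as the intermediate filament desmin, Des (1.56, adjusted p = 0.03346).

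Lists of immune cell and fibroblast markers passed as sets in cKO hearts, with few single calls and none of the set calls kept with an estimated correlation, and those of endothelial cells and smooth muscle did not pass. The macrophage and monocyte list had a median log2 fold change of 0.82 over 23 members (camera, adjusted p = 9.93e-05, 0.138 as the p with an estimated correlation). It had 1 call over all genes, Ccr2, the receptor of recruited monocytes (4.12-fold, 12.43 ± 1.795 against 3.022 ± 0.5748 CPM, adjusted p = 0.04929), and 7 higher and 1 lower when adjusted over the list alone. Its median was 1.45 without flox replicate 3, with 13 called higher, such as Lgals3 (4.01, adjusted p = 0.005273), and 1 lower, Timd4, a marker of resident macrophages (-2.29, adjusted p = 0.02153). Lymphocyte and neutrophil markers had a median of 1.64 over 19 members (adjusted p = 0.00333, 0.132 as the p with an estimated correlation), with 0 called, and 2 when adjusted over the list alone, and 3 without flox replicate 3, but only 4 of the 19 reached 1 CPM in flox hearts. Inflammatory cytokines and chemokines had a median of 0.80 over 25 members (adjusted p = 2.94e-05, 0.139 as the p with an estimated correlation) and 1.68 without flox replicate 3. Cxcl10 was called (6.62-fold, adjusted p = 0.03872), and 6 were when adjusted over the list alone. Interferon response genes had a median of 0.89 over 30 members (adjusted p = 9.85e-09, 0.124 as the p with an estimated correlation), with 0 called, 10 when adjusted over the list alone, and 13 without flox replicate 3, among them Ifit3 (1.96, adjusted p = 0.01821). With scaling to total counts alone the macrophage, cytokine and interferon medians were larger, at 1.61, 1.86 and 1.41. With the length correction the first 2 were 1.27 and 1.47.

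Fibroblast markers had a median of 0.85 over 16 members (camera, adjusted p = 0.000205, 0.132 as the p with an estimated correlation), with 0 called over all genes and 7 higher and 1 lower when adjusted over the list alone, and 6 and 1 called without flox replicate 3. With total counts alone the median was 1.31. Islr and Lum had log2 fold changes of 1.46 (SE 0.31) and 1.42 (SE 0.33). The endothelial list had a median of -0.13 and a mean of 0.05 over 18 members (adjusted p = 0.956), and the smooth muscle and pericyte list a median of -0.11 and a mean of 0.04 over 15 (adjusted p = 0.956). With scaling to total counts alone these medians were 0.41 and 0.24, and without flox replicate 3 they were -0.14 and -0.52. Cnn1, calponin 1, was the 1 smooth muscle marker called (9.3-fold higher, adjusted p = 0.03872), while Acta2 was at 131 ± 42.35 against 322.2 ± 95.78 CPM (log2 fold change -1.30, adjusted p = 0.2205, and -0.62 with total counts alone).

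**Figure D4:**
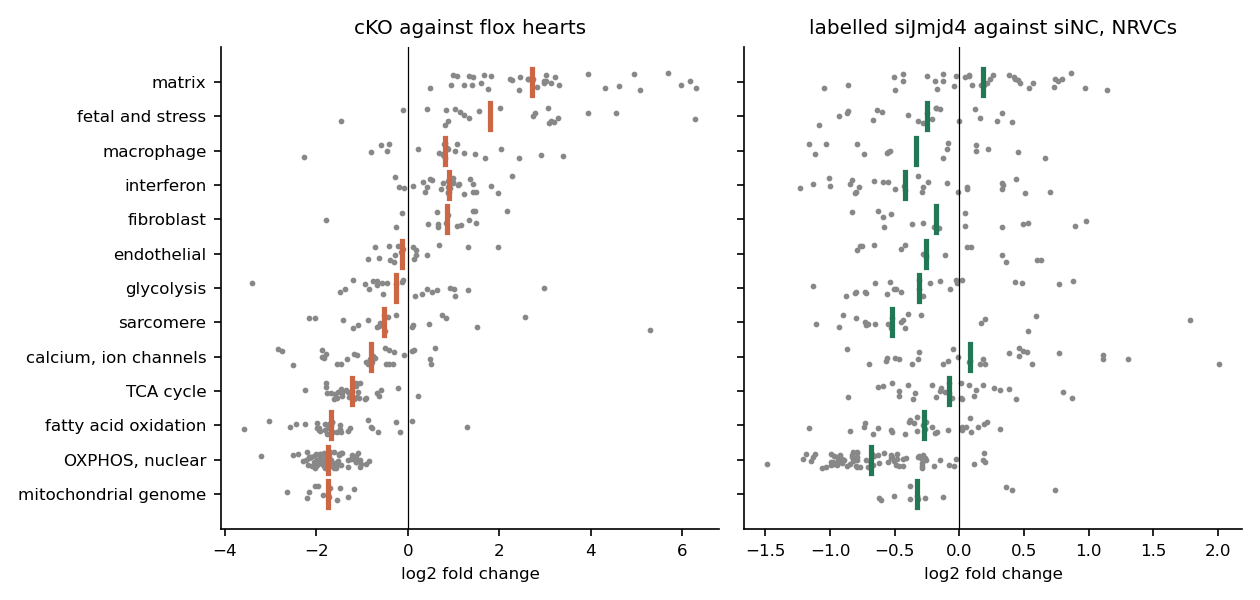
Log2 fold change of each tested member of 13 fixed gene lists in cKO against flox hearts and in NRVCs labelled siJmjd4 against siNC (points, genes, spread vertically for display; bar, median; the horizontal scales differ). In the hearts the medians run from 2.72 for matrix genes to -1.75 for nuclear-encoded subunits of oxidative phosphorylation, and in the NRVCs from 0.18 to -0.69 for the same lists.

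The NRVC comparison asks what a knockdown of Jmjd4 changes in isolated cardiomyocytes. In edgeR's test with all 6 libraries 1 gene differed. Myh9l1, a gene named after the non-muscle myosin heavy chain gene Myh9, had 0 counts in all 3 siNC libraries and 785, 849 and 971 CPM (868 ± 94.2, SD, n = 3) in the libraries labelled siJmjd4. That is at least 13900-fold higher, from the lowest of these against a floor of 3 counts per library, and the adjusted p was 0.004339. Myh9 was at 1210, 1250 and 671 CPM in the siNC libraries and at 1370, 1500 and 1740 CPM in the others, and how the counting shared reads between the 2 genes is not given in the sources used here.

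Of 15497 rat genes tested, 1 was higher and 0 lower, with 1350 at an unadjusted p under 0.05, where chance gives 775, and DESeq2's Wald test called 136 higher and 32 lower. Without siNC replicate 3, edgeR called 77 higher and 13 lower. Among these were Runx1t1, a transcriptional corepressor (log2 fold change 1.56, adjusted p = 0.005539), Nrk, a kinase (2.07, adjusted p = 0.04087), and Capns1, the small calpain subunit, which was lower (30.65 ± 5.224 against 90.97 ± 8.789 CPM over all 6 libraries, adjusted p = 0.005972 without siNC replicate 3). These genes did not pass with all 6 libraries (adjusted p = 0.379 for Runx1t1 and Nrk and 0.2977 for Capns1). Of the 90 genes called, 66 had a transcript length, and 0 of these were called with the length correction and all 6 libraries. Some calls rest on counts of 0. Nhp2 (log2 fold change 13.63) had 0 counts in siNC replicates 1 and 2 but 62.47 CPM in siNC replicate 3. Without siNC replicates 1 or 2 edgeR called 4 or 2 higher, and without any library labelled siJmjd4 it called 0, with 339 to 834 genes at an unadjusted p under 0.05.

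As sets, 4 of the 29 lists were lower in the libraries labelled siJmjd4 and 0 higher. That number does not set the real grouping apart. Of the 10 splits of these libraries into 3 and 3, 6, the real one included, gave as many lists, and the highest other gave 9. The nuclear-encoded subunits of oxidative phosphorylation had a median log2 fold change of -0.69 over 74 members (camera, adjusted p = 7.55e-12), sarcomere and Z-disc genes of -0.52 over 21 (adjusted p = 0.00278), fatty acid uptake and oxidation of -0.28 over 30 (adjusted p = 0.00945) and glycolysis of -0.31 over 25 (adjusted p = 0.0255). No member was called, nor was any when adjusted over the list alone, and with an estimated correlation each of the 4 lists had an adjusted p = 0.722. Examples were Cox6a2, a muscle subunit of cytochrome oxidase, at 391 ± 75.39 against 866.3 ± 553.3 CPM, Tnni3, cardiac troponin I, at 213.5 ± 29.79 against 371.4 ± 134.1 CPM, Fabp3, the heart fatty acid-binding protein, at 160.9 ± 31.34 against 248.5 ± 71.63 CPM, and Tpi1, a glycolytic enzyme, at 140.5 ± 14.4 against 259.5 ± 115.7 CPM (SD, n = 3, adjusted p = 0.379 for each). Without siNC replicate 3 the medians of these lists were -0.24, -0.26, -0.20 and -0.16 in the same order, and after a correction for transcript length they were -0.09, -0.29, -0.12 and -0.17. The log2 fold changes of Cox6a2, Tnni3, Fabp3 and Tpi1 were -1.15, -0.80, -0.63 and -0.88 with all 6 libraries and -0.48, -0.46, -0.36 and -0.46 without siNC replicate 3. With total counts alone the fatty acid and glycolysis medians were -0.18 and -0.19.

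The matrix list, which rose in the hearts, had a median of 0.18 over 36 members in the NRVCs (adjusted p = 0.228), of 0.06 without siNC replicate 3 and of -0.08 with the length correction. The fetal and stress list had one of -0.25 over 21 (adjusted p = 0.141). Lox had a log2 fold change of 0.73 (adjusted p = 0.379) and Nppa one of -0.64, at 4417 ± 593.9 against 6899 ± 2210 CPM (adjusted p = 0.379). Nppa was at 9439 CPM in siNC replicate 3 against 5420 and 5837 in replicates 1 and 2. Its log2 fold change was -0.35 without that library and -0.02 with the length correction. The other metabolic lists did not pass either, with medians of -0.08 for pyruvate oxidation and the TCA cycle (adjusted p = 0.245), -0.32 for mitochondrial genome transcripts (adjusted p = 0.184), -0.05 for mitochondrial gene regulators (0.958) and 0.08 for branched-chain amino acid and ketone body breakdown (0.958). Calcium handling and ion channel genes had a median of 0.08 (adjusted p = 0.744). Markers of other cell types had medians of -0.18 for fibroblasts (adjusted p = 0.48), -0.26 for endothelial cells (0.374), -0.17 for smooth muscle and pericytes (0.672) and -0.34 for macrophages and monocytes (0.228). Most of these medians were smaller or turned without siNC replicate 3 or with the length correction. They came, respectively, to -0.16 and 0.23 for mitochondrial genome transcripts, -0.05 and 0.17 for their regulators, -0.09 and 0.08 for branched-chain amino acid breakdown, -0.04 and -0.10 for calcium handling, -0.14 and 0.01 for fibroblasts, 0.03 and -0.07 for smooth muscle, and -0.11 and 0.03 for macrophages. Without siNC replicate 3, camera called 3 of these lists lower, namely pyruvate oxidation and the TCA cycle (median -0.13, adjusted p = 0.00656), fetal and stress genes (-0.17, adjusted p = 0.011) and endothelial markers (-0.26, adjusted p = 0.0241), each with an adjusted p = 0.942 with an estimated correlation. With the length correction these 3 medians were 0.13, -0.16 and -0.15. The fetal and stress list was also called lower without siJmjd4 replicate 1 (adjusted p = 0.0241), but its adjusted p with an estimated correlation was 0.722 with all 6 libraries.

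The systems were then compared gene by gene. The response differed between them in 264 of the 11848 genes tested in a model of all 12 libraries, with the change in the hearts above that in the NRVCs for 214 and below it for 50. That model fits a dispersion per gene shared by both systems, while the common dispersion was 0.284 in the mouse and 0.142 in the rat. It may thus understate the spread between hearts, and the count is read with that limit. Nox4, an NADPH oxidase, rose 23.6-fold in cKO hearts (15.45 ± 2.407 against 0.657 ± 0.1359 CPM), with a log2 fold change of 4.56 there and of 0 in the NRVCs (difference 4.57, SE 0.38, adjusted p = 0.000241). Frzb, a secreted Wnt antagonist, rose 17.6-fold in the hearts, with log2 fold changes of 4.14 and -0.24 (difference 4.38, SE 0.37, adjusted p = 0.000241). For Nppa the difference was 6.93 (SE 0.69, adjusted p = 0.001013). Cracr2b, a calcium channel regulator, had 331 to 537 counts in the siNC libraries and 0 in all 3 libraries labelled siJmjd4, at least 110-fold lower (adjusted p = 0.2568 in the NRVC fit), and a log2 fold change of -0.06 in the hearts (adjusted p of the difference 0.000241).

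No gene was called in the same direction in both systems. Of 11850 genes tested in both under the same symbol, 47 were higher and 8 lower in the hearts in edgeR's test and 0 and 0 in the NRVCs, so that 0 shared calls were all that could arise. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.104 and a Spearman rho of 0.152, and 56.7% had the same sign. Without flox replicate 3 and siNC replicate 3, r was -0.064, 0 genes were higher in both where 3.44 were expected (Fisher's exact test, two-sided, p = 0.04957). Pkia, a protein kinase A inhibitor (-1.27 in the hearts, 0.60 in the NRVCs), and Ppm1k, a phosphatase of branched-chain amino acid breakdown (-2.30 and 1.07), were lower in the hearts and higher in the NRVCs, which is no more than chance gives (Fisher's exact test, p = 1). The model of the difference gave 1837 genes without these 2 libraries, and from 59 (without siJmjd4 replicate 3) to 984 (without flox replicate 3) when any 1 of the 12 was left out.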

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

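The test of a difference between the systems was planned before the data were examined, and the test of other splits of the samples with it. Responses differed between cKO hearts and NRVCs labelled siJmjd4 in 264 genes, among them Cracr2b, Nox4 and Frzb (adjusted p = 0.000241 each) and Nppa (adjusted p = 0.00101), as tested by the interaction in 1 model. Of 100 combined splits of both sets of libraries, 1, the real one, gave as many genes, and the highest other split gave 169, a share under 0.05. The 90 splits with other mouse groups gave at most 3 genes, however, so this share mostly restates the difference between the heart groups. With the true mouse groups kept, the real split gave 264 and the 9 others 104 to 169, and these 10 are too few for a share under 0.05, so chance is not excluded for the part of the count that rests on the rat groups. The systems also differ in species, age, tissue against culture, and time after treatment, and only the cKO hearts carry Cre. None of these was tested apart. Jmjd4 was not detectably lower in the libraries labelled siJmjd4 (log2 fold change 0.25, adjusted p = 0.7698 in edgeR's test). The 264 genes thus cannot be read as unlike responses to a loss of Jmjd4.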

How the results depend on the processing

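The transcript length correction, sample quality weights, total-count scaling, the mitochondrial genes left out and the pairs of libraries left out were chosen after seeing the data. In cKO hearts (67 higher, 25 lower), counts were 104 and 42 with no filter, 730 and 536 with the length correction, 20 and 0 with total counts alone, 1793 and 1792 without flox replicate 3 and cKO replicate 2, 957 and 791 with DESeq2, 2164 and 1687 with voom weights, 0 to 813 and 0 to 560 when 1 library was left out, and 0 and 0 with the replicate number as a block (1591 at an unadjusted p under 0.05). All 92 called genes kept their sign in each of these with a value, 81 having one in the length correction and 79 staying called there. DESeq2's size factors, the 5 CPM filter and the 2-fold threshold stayed within 1.5 times. Total counts alone turned the log2 fold change of Pkm to 0.45. Of the 20 heart lists, an estimated correlation left 1 higher and 0 lower, and fry 11 higher and 3 lower, with p53 targets newly higher under fry (adjusted p = 0.00923), while 18 were called whichever library was left out. The exceptions were the integrated stress response without cKO replicate 2 (adjusted p = 0.0605) and the erythroid list without flox replicate 3 (0.125). In the NRVCs (1 higher, 0 lower), counts were 136 and 32 with DESeq2, 974 and 174 with voom weights, 0 to 77 and 0 to 13 when 1 library was left out, and 0 and 0 with the block (472 at an unadjusted p under 0.05) and with the length correction (1084), where Myh9l1 has no length. Of the 4 NRVC lists an estimated correlation and fry left 0, and 3 to 8 were called when 1 library was left out. Glycolysis was lost without siJmjd4 replicate 2 (0.0673). The rat Jmjd4 log2 fold change was -0.17 with voom weights and -0.16 to 0.66 when 1 library was left out. Shared higher calls were 2 at an unadjusted p under 0.01 (5.17 expected), and 55 without flox and siNC replicates 3 at that threshold (93.89 expected, Fisher's exact test, p = 3.217e-06), with 6 shared lower (11.15 expected). In that setting 30 genes were higher in the hearts and lower in the NRVCs, and 57 the reverse (Fisher's exact test for the latter, p = 0.9428). Genes are not independent replicates in these tests. Genes differing between the systems were 0 with the block (1194 at an unadjusted p under 0.05), 1837 without the same 2 libraries and 59 to 984 when 1 library was left out. Same-numbered samples mostly did not deviate together (correlations 0.36, -0.48 and -0.33 in the mouse and -0.14, -0.02 and -0.15 in the rat), and only flox and cKO replicate 1 matched best with their own number. The length trends of flox replicate 3 and cKO replicate 2, and of siNC replicate 3 and siJmjd4 replicate 1, fall on unlike numbers. This check therefore cannot exclude a pairing. For 70 mouse genes, 1111 values under alternatives fell into 721 with the same call, 175 no longer called, 214 newly called and 1 reversed. For 14 rat genes, 192 gave 174, 4, 12 and 2, and for 5 genes of the systems comparison, 75 gave 70, 5, 0 and 0. Apart from the length correction, library weights and left-out libraries, which change the spread by construction, the cause of these shifts was not tested. Pseudocounts, median centring and quantile normalization were planned for normalized values and did not apply to counts. Changes of 2-fold were mostly beyond this design with all 6 libraries.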

Other observations

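The called heart genes in this paragraph were chosen after their values were seen. Wisp2, a matricellular protein, rose 26.2-fold in cKO hearts (126.5 ± 28.88 against 4.842 ± 1.307 CPM, SD, n = 3, adjusted p = 0.02551), Nkd2, an inhibitor of Wnt signalling, 15.6-fold (adjusted p = 0.03364), the Wnt receptor Fzd2 7.92-fold (adjusted p = 0.02691) and Wisp1 7.26-fold (adjusted p = 0.0414). Tgfb3 rose 5.43-fold (adjusted p = 0.04899), Meox1, a transcription factor, 7.09-fold (adjusted p = 0.03872) and the acute phase gene Serpina3n 19.5-fold (155.2 ± 16.31 against 7.961 ± 1.098 CPM, adjusted p = 0.02551). Dio2, which activates thyroid hormone, rose 23.5-fold (adjusted p = 0.02551). Scn4b, a sodium channel subunit, fell 6.91-fold (1.814 ± 0.5274 against 12.54 ± 2.313 CPM, adjusted p = 0.03872).

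Of the fixed lists not yet described, several were higher in cKO hearts. Cell cycle genes had a median log2 fold change of 1.39, with 36 of 39 members higher (camera, adjusted p = 2.62e-08, 0.332 as the p with an estimated correlation), but 0 called over all genes or adjusted over the list alone. Immediate early genes had a median of 0.83 over 23 (adjusted p = 1.06e-06, 0.23 with an estimated correlation), with 0 called over all genes and 6 when adjusted over the list alone, such as Egr2 (5.45) and Myc (1.80). The integrated stress response had 0.38 over 29 (adjusted p = 0.00654, 0.197 with an estimated correlation, 0.0605 without cKO replicate 2, and a median of 0.65 without flox replicate 3), with 0 called and 1 when adjusted over the list alone, Gdf15 (3.10, adjusted p = 0.05737 over all genes). Atrial markers had 0.75 over 12 (adjusted p = 0.0196, 0.195 with an estimated correlation), with Nppa called, 4 higher and 2 lower when adjusted over the list alone, and 5 members held by other lists. Adipocyte and mesothelial markers had 0.83 over 9 (adjusted p = 0.00363, 0.133 with an estimated correlation), with Krt8 called and 2 when adjusted over the list alone. Erythroid markers were lower, -1.21 over 10 (adjusted p = 0.00178, 0.351 with an estimated correlation, 0.125 without flox replicate 3), with 0 called in either way. The other lists did not pass, namely p53 targets (0.23 over 27, adjusted p = 0.267, 0 called and 3 when adjusted over the list alone, but higher with fry at 0.00923, which does not compare the list with other genes), heat shock proteins and chaperone-mediated autophagy (-0.09 over 28, 0.586), hypoxia (-0.06 over 23, 0.262), antioxidant response (-0.16 over 25, 0.956, and higher without flox replicate 3 at 0.0289, or 0.551 with an estimated correlation as well) and the JmjC family with JMJD4 partners (-0.21 over 13, 0.262). Scaling to total counts alone gave each of these 4 last medians the opposite sign, at 0.53, 0.64, 0.72 and 0.45. Leaving out flox replicate 3 turned the first 3 as well, to 0.07, 0.26 and 0.53. The JmjC median was -0.08 without that library and -0.35 with the length correction, which turned the hypoxia and antioxidant medians to 0.09 and 0.01 and gave 0.49 for p53 targets. With total counts alone the medians were 1.31 for immediate early genes, 0.99 for the integrated stress response, 1.31 for atrial, 1.40 for adipocyte and mesothelial and -0.49 for erythroid markers, and 1.00 for p53 targets. Without flox replicate 3 the members called higher and lower were 6 and 0 of the immediate early genes, 5 and 2 of the integrated stress response, 4 and 2 of the atrial markers, 2 and 0 of the adipocyte and mesothelial markers, 4 and 2 of the p53 targets, 3 and 2 of the heat shock list, 2 and 0 of the hypoxia list, 4 and 1 of the antioxidant list, and 0 of the cell cycle, erythroid and JmjC lists.

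In the NRVCs none of the lists left passed with all 6 libraries. Medians were -0.20 for lymphocyte and neutrophil markers (adjusted p = 0.566), 0.12 for inflammatory cytokines (0.701), -0.42 for interferon response (0.228, but 0.00661 without siNC replicate 1 and 0.0254 without siJmjd4 replicate 3, against 0.815 with an estimated correlation and all 6 libraries), -0.16 for the integrated stress response (0.461), 0.02 for heat shock proteins (0.364), 0.07 for p53 targets (0.567), 0.10 for the cell cycle (0.525), 0.11 for hypoxia (0.567), -0.35 for the antioxidant response (0.228, and 0.0268 without siNC replicate 3, or 0.942 with an estimated correlation as well), 0.18 for immediate early genes (0.374), -0.50 for atrial markers (0.217), 0.04 for the JmjC family (0.883), -0.46 for erythroid (0.24) and -0.39 for adipocyte and mesothelial markers (0.374). Leaving out siNC replicate 3 gave, in the same order, -0.49, -0.01, -0.36, 0.03, -0.03, -0.01, 0.03, 0.03, -0.11, -0.02, -0.13, -0.04, -0.24 and 0.06. The length correction gave -0.18, 0.31, -0.21, 0.07, -0.05, 0.15, -0.01, 0.20, -0.01, 0.30, -0.03, 0.13, -0.05 and -0.05. Most of these medians thus moved by over 1.5 times or turned. The p53 target Tp53inp1 was the 1 member of any list that passed when adjusted over its list alone (log2 fold change 1.74, SE 0.33, adjusted p over all genes 0.379, and 0.03589 without siNC replicate 3).

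The counts of other splits were planned. The tests below of the Myh9l1 zeros and of mitochondrial crowding were chosen after the values were seen, and the others before their results. The crowding test replaced one written before its result, the number of genes called with mitochondrial genes left out (84 against 92), which was set aside because it could not tell the cases apart. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For heart genes the real split gave 92 and the highest other 0 (1 of 10 as large), and for heart lists 20 and 14 (1 of 10), with at least 7 lists in every other split. For NRVC genes it gave 1 and the highest other 2 (3 of 10), and for NRVC lists 4 and 9 (6 of 10), so neither NRVC count stood above the other splits.

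Flox replicate 3 and siNC replicate 3 stood apart. A heart of the other genotype labelled as flox is argued against, since 69.6% of 1371 genes, those of the 1373 called without it that were also tested with all 6 libraries, lay closer to flox replicates 1 and 2 than to the cKO mean in it. Esr1, whose counts may include reads of the transgene, was at 0.508 CPM in flox replicate 3. In cKO replicates 1, 2 and 3 it was at 1070, 824 and 474 CPM. Mitochondrial transcripts crowding out the rest, which would lower nuclear genes alike, are argued against as the whole cause, since the median log2 ratio of nuclear genes with the shortest transcripts lay 2.80 (SE 0.034) above that of those with the longest. The SE is over genes, not libraries. This difference and the rho of flox replicate 3 below describe the same trend with transcript length, so they are not separate tests. Loss of long transcripts, as in broken RNA, may be the explanation, since across genes the log2 ratio fell with transcript length in flox replicate 3 (rho -0.62) and in siNC replicate 3 (rho -0.48), though not in them alone, as cKO replicate 2 had a rho of -0.55 and siJmjd4 replicate 1 of -0.37 against their own groups. RNA integrity values were not used here, and no biological explanation within a control group was tested.

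The Myh9l1 counts, 0 in all siNC libraries and 53244 or more in each library labelled siJmjd4, may come from counting in which a gene's reads go to another name in some libraries. The real split had 4 genes at 0 on 1 side with 20 or more counts in each library on the other, and the highest of the other splits had 6, so such zeros also occur across the groups. Hsp90aa1, an abundant chaperone, had 0 counts in siNC replicates 1 and 3 and siJmjd4 replicate 2 and 11761 or more in the other 3. What stays open is a real change of Myh9l1, whose lowest count lies above that of the leading gene of every other split. Cracr2b is 1 of the 4 genes, so its zeros are as open.

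The rise of matrix genes with the lower energy genes in cKO hearts could come from RNA quality, cell composition, Cre or the loss of Jmjd4. Unequal loss of long transcripts as the whole cause is argued against for the matrix, fatty acid and TCA cycle lists. After the length correction their medians kept 98.9%, 100.3% and 96.7% of their size. The oxidative phosphorylation and mitochondrial genome lists kept 61.8% and 60.2%. Without flox replicate 3, however, their medians went from -1.75 and -1.74 to -0.54 and -0.71, so for these lists the question stays open. A lower share of cardiomyocyte RNA is argued against as the whole cause, since the sarcomere median was -0.53 (bootstrap SE 0.20) where it needed -0.85. Without flox replicate 3 it was 0.10 (SE 0.14) where it needed -0.41. The bootstrap resampled list members, so its SE does not measure the spread between hearts. Of the 23 sarcomere members, 8 had higher values in cKO hearts, so the list is not a pure measure of that share. Marker medians of other cells moved apart, from 1.64 (SE 0.39) for lymphocytes and neutrophils and 0.85 (SE 0.20) for fibroblasts to -0.13 (SE 0.16) for endothelial cells (1 of whose 18 members another list holds, Fabp4 at 768 CPM in flox hearts being the most abundant) and -1.21 (SE 0.17) for blood. The Cre transgene and the loss of Jmjd4 cannot be told apart, since no heart with Cre and intact Jmjd4 was analysed here, and the p53 target list (median 0.23), called higher by fry (adjusted p = 0.00923) and not by camera (0.267), does not separate them.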
